A study of Mus musculus with 4 samples.

How the data were processed

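Mature miRNAs were measured in CD4+CD25+ cells sorted magnetically from the spleens of female BALB/c mice. The sample titles name them regulatory T cells (Treg), which restrain other immune cells. The arrays do not show what share of the sorted cells were regulatory T cells, so values describe the sorted fraction. There were 2 samples from uninfected mice (day 0) and 2 from mice taken on day 4 after injection of 1000000 red cells carrying Plasmodium yoelii 17XL, a lethal rodent malaria parasite. Each sample was hybridised alone, labelled with Cy3, to an Agilent mouse miRNA array with 1881 miRNAs, 4415 probes and 56430 miRNA spots. The series design text names another array maker, but the headers and columns of the files are Agilent's. The labelling text in the labels describes a linear amplification of cRNA, a step usual for messenger RNA, and how the miRNAs themselves were labelled is not given in the sources used here.

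Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.1.1, with spatial detrending on. Per the file headers, their processed signal is an intensity per spot that was background-subtracted within the array before deposit and not normalized between arrays. The authors also deposited a table of log2 values for 278 miRNAs. Its method, filter and centring are not given in the sources used here, and its direction is that of signal. The column medians were 4.13, 4.15, 4.13 and 4.13 for uninfected replicates 1 and 2 and infected replicates 1 and 2, and all 4 columns shared a 75th percentile of 5.87 and a maximum of 15.7, as after quantile normalization. Its values ranked with the mean signal over a miRNA's probes (Spearman's rho across miRNAs from 0.996 to 1.000). They ranked less closely with the files' own total gene signal (rho from 0.703 to 0.818). That total gene signal was a fixed multiple of the sum over a miRNA's own probes for most miRNAs, 0.212 on 3 arrays and 0.275 on infected replicate 1. It departed from that multiple by over 2-fold for 52, 41, 78 and 60 miRNAs on the 4 arrays in the same order, 127 miRNAs in all, among those whose probes summed to over 20. The total gene signal was therefore used only in alternatives. Values in infected replicate 1's file that are written in scientific notation carry 3 significant digits.

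From the processed signals, control spots and spots flagged as outliers (2.31% to 2.78% of spots) were left out. A probe counted as detected on an array when at least 0.5 of its remaining spots were well above background. Each array was divided by its 75th percentile over the 382 probes detected on all 4 arrays. Scaled signals were floored at 0.0659, the median over arrays of the 1st percentile of detected spots, and log2 was taken. Spots were averaged per probe, and a miRNA was the mean over its probes detected on both arrays of at least 1 group. This left 267 miRNAs to test and 1614 untested. Of the 195 with several such probes, 11 had probes of opposite sign. Near-identical family members (let-7, miR-15/16, miR-29, miR-30, miR-181, miR-17) can bind each other's probes, so values within a family are not independent.

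Infected and uninfected arrays were compared with limma 3.58.1 (lmFit and eBayes, group only, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Files were read with data.table, version 1.17.8. The prior degrees of freedom came out as infinite, so every miRNA shared a standard error of 0.49 on the log2 scale. Fixed miRNA lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over 10 lists. Where a miRNA was not well above background on any array of a group, the difference is given as a lower bound: the bright group's mean against the mean, per array, of the lowest detected probe or the miRNA's own value, whichever was higher. An exact permutation of 2 arrays against 2 cannot give a two-sided p under 0.333. The labels do not say whether the samples came from separate mice or pools, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

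The miRNAs named were set by rule before the data were examined: in each direction the 10 largest differences past the threshold, filled with the largest differences whose arrays do not overlap, up to 4 members of each list by p-value, and 10 fixed names. The lists, and all alternatives except the labelling spike-in scaling, the unmoderated variance and the concordant total gene signal, were fixed at the same time. The alternatives covered scaling, background correction (normexp with an offset of 50), probe summary, the deposited values, filters, floor, variance model, replicate number and slide as blocks, each array left out, and thresholds. The normexp offset shrinks the log2 differences of dim miRNAs by construction. Host genes came from the RefSeq gene table of assembly GRCm38.p6 by overlap, without regard to strand. The files name no build, so no coordinates are given.

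The steps were tested on simulated data in 20 sets built from the real probe means, with 40 of about 278 miRNAs changed, as many up as down. The changed miRNAs were drawn from those above the median level, and every miRNA received independent noise of the same SD. The shares called and the false calls therefore do not carry over to dim miRNAs or to miRNAs that vary together. At the measured spread (SD 0.486 on the log2 scale), 9.75% of 2-fold and 57.5% of 4-fold changes were called, with 0.15 false calls per set and median log2 sizes of 1.01 and 1.98. At a smaller spread (SD 0.122), 100% of both were called, with 1.55 false calls per set. When all 40 went up at that smaller spread, the percentile itself moved: unchanged miRNAs took a median log2 difference of -0.49 and 227.8 per set were called falsely. Scaled values therefore show changes relative to the bright miRNAs of the same array.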

Results

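CD4+CD25+ spleen cells, titled regulatory T cells, of uninfected mice (n = 2 arrays) and of mice on day 4 of Plasmodium yoelii 17XL infection (n = 2 arrays) were profiled for mature miRNAs. Spots well above background made up 13.5% and 10.5% of miRNA spots on uninfected replicates 1 and 2, and 13.9% and 11.6% on infected replicates 1 and 2. At least 1 probe was detected for 294, 232, 308 and 259 miRNAs, in the same order. Infected replicate 1 was the brightest array, with a 75th percentile of 405.0 against 218.8, 217.6 and 230.2, while its labelling spike-in dmr_285 read 1759 against 1489, 1444 and 1255. Its hybridisation spike-ins were the lowest, dmr_3 at 8110 against 19062, 12955 and 12482, and dmr_6 at 911 against 3530, 1348 and 1133. Both were highest on uninfected replicate 1. Uninfected replicate 1 lay alone on slide 1, and the other 3 arrays shared slide 2 and its scan. Values below are log2 signals relative to the array's 75th percentile, as mean ± SD over 2 arrays.

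The series design sets infected against uninfected mice. In the infected arrays 5 of 267 tested miRNAs rose, and 0 fell by limma (14 higher and 4 lower at an unadjusted p under 0.05). Of the tested miRNAs, 15 were detected on both infected arrays and no uninfected array, and 0 the other way round. The filter was the same for both groups, but on these arrays it admitted such miRNAs only in the upward direction. Uninfected replicate 2 had the fewest detected probes, 419 against 533 on uninfected replicate 1 and 568 and 476 on infected replicates 1 and 2. Of the 3 called miRNAs detected in both groups, miR-7050-5p had the largest difference, rising from -2.11 ± 0.13 to 0.10 ± 0.53 (n = 2 each), a log2 difference of 2.21 with a standard error of 0.49 and an adjusted p of 0.00181. miR-697 rose from -3.66 ± 0.16 to -1.84 ± 0.46 (log2 difference 1.82, adjusted p = 0.0178) and miR-6965-5p from -2.10 ± 0.16 to -0.36 ± 0.53 (log2 difference 1.74, adjusted p = 0.0208). The uninfected values of miR-697, -3.55 and -3.77, lay close to the log2 floor of -3.92. miR-3099-3p and miR-6921-5p were not well above background on either uninfected array and were detected on both infected arrays, at least 3.45-fold higher (adjusted p = 0.0178) and at least 3.23-fold higher (adjusted p = 0.0208). Both belong to the 15 above, and their adjusted p came from uninfected values at or near the floor. In the GRCm38.p6 gene table the genes of these miRNAs overlap Fxyd5 (miR-7050), Sf3a3 (miR-697), Ccnf (miR-6965), Usp29 (miR-3099) and Srebf1 (miR-6921), the last encoding a regulator of lipid synthesis. Each was higher in 2 of 2 infected arrays than in either uninfected array.

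These calls come from limma, with Benjamini-Hochberg adjustment. With a single array left out, the 5 log2 differences were 1.38 to 1.86 without infected replicate 2 and 1.62 to 2.58 without any other array. No miRNA was called when each kept its own variance, or with slide as a block. With the block the 5 differences were 1.76 to 2.30 on the log2 scale against 1.74 to 2.21, and their standard error was 0.63. The block sets aside uninfected replicate 1, alone on slide 1. By construction it gives the contrast within slide 2, which holds 1 uninfected and 2 infected arrays. None was called either under quantile normalization (differences of 1.71 to 2.19), no scaling (2.08 to 2.69), spike-in scaling (2.00 to 2.47), total gene signal (1.61 to 3.25), no filter on dim miRNAs (1.74 to 2.21) or normexp background correction (0.47 to 1.36). With a higher floor 1 was called, 2 among miRNAs detected on all 4 arrays, which include 3 of the 5, and 3 with the concordant total gene signal. The deposited values gave 10 calls. They include 4 of the 5, at differences of 1.74 to 7.83, and call 1 of them (miR-6921-5p, the largest of these differences). As miR-6921-5p was not well above background on either uninfected array, the size of that difference is not well measured.

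The next largest positive differences did not pass the test. They were miR-1231-5p (log2 difference 1.47, adjusted p = 0.114), miR-202-3p (1.31), miR-7036a-5p (1.25), miR-3473g (1.20) and miR-7048-5p (1.20), the last 4 with adjusted p from 0.277 to 0.368. None of the 10 largest negative differences among miRNAs whose arrays do not overlap passed either. miR-142a-3p, a miRNA of blood-forming lineages, stood at 0.10 ± 0.31 in uninfected and -1.01 ± 0.58 in infected arrays (log2 difference -1.11, adjusted p = 0.546). miR-125a-5p (-1.05), miR-23a-3p (-0.99), miR-677-3p (-0.94), miR-155-5p (-0.94), miR-181a-5p (-0.93), let-7e-5p (-0.93), miR-331-3p (-0.91), miR-1839-3p (-0.85) and miR-342-5p (-0.82) had adjusted p from 0.691 to 0.745. miR-125a-5p and let-7e-5p were detected on only 1 of the 2 infected arrays.

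**Figure D1:**
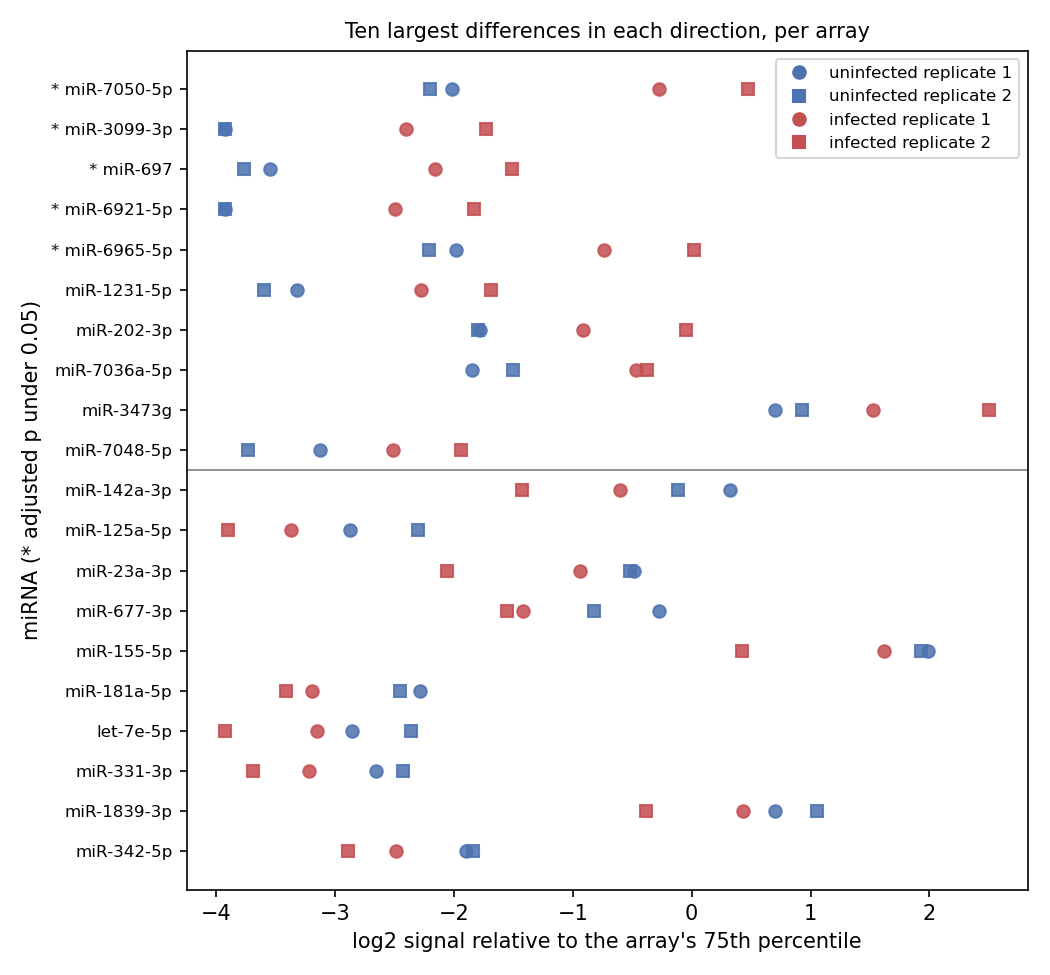
Log2 signal relative to the array's 75th percentile (x axis) of the 10 largest positive (top) and 10 largest negative (bottom) differences among miRNAs whose arrays do not overlap between groups. There is 1 point per array, blue for uninfected and red for infected, circles for replicate 1 and squares for replicate 2. An asterisk marks an adjusted p under 0.05. miR-7050-5p lies at -2.02 and -2.20 in uninfected and -0.27 and 0.47 in infected arrays.

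A count that does not use the moderated variance gave 14 miRNAs at least 2-fold apart with no overlap of the arrays, 12 higher and 2 lower in infected arrays. Groups did not overlap for 31.8% of tested miRNAs, where chance gives 33.3%. Splitting the arrays by replicate number instead gave 15 miRNAs at least 2-fold apart with no overlap, and the remaining split gave 4. Neither of these other splits gave a limma call (16 and 0 at an unadjusted p under 0.05, against 18 for infection), but they were fitted with prior degrees of freedom of 3.72 and 4.95 where the infection split had an infinite prior, so the numbers of calls are not on equal terms. Across miRNAs, which are not independent replicates, Pearson's r was 0.948 between the uninfected arrays and 0.929 between the infected arrays. Between groups it was 0.969 for the arrays numbered replicate 1 and 0.906 for those numbered replicate 2, 0.916 between uninfected replicate 1 and infected replicate 2, and 0.935 between uninfected replicate 2 and infected replicate 1. Both arrays numbered replicate 2 thus correlated best with the other array of their group, and both numbered replicate 1 with each other. The SD of log2 differences was 0.64 within the uninfected pair, 0.73 within the infected pair, and 0.49 to 0.85 between groups.

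Of the lists fixed beforehand, only the T cell quiescence list, miRNAs abundant in resting T cells, shifted past the threshold. Camera gave an adjusted p of 0.00532 with the preset correlation of 0.01, which treats members as nearly independent. The estimated correlation between members was 0.93, and with it camera gave an adjusted p of 0.693. Fry gave an adjusted p of 0.692. Camera values of other lists below use the preset correlation, where the estimates ran from 0.34 (Sfmbt2 cluster) to 0.93. All 13 of its tested members were lower in infected arrays, with a median log2 difference of -0.54, but 0 were called singly, 0 when adjusted over the list alone. Its members miR-30b-5p (log2 difference -0.86), miR-26b-5p (-0.86) and miR-150-5p (-0.56) did not pass the test. Only the members miR-30a-5p, miR-140-3p and miR-342-3p had groups that did not overlap. The list's mean relative to the uninfected mean was -0.10 in infected replicate 1 and -0.90 in infected replicate 2, and -0.27 and 0.27 in the uninfected replicates 1 and 2. Without infected replicate 2 the mean difference was -0.07, and without uninfected replicate 2 it was -0.23. It was -0.89 without infected replicate 1 and -0.77 without uninfected replicate 1. With slide as a block it was also -0.77. The block sets aside uninfected replicate 1, alone on slide 1, so it gives the contrast within slide 2 and is no separate check. The mean difference of -0.50 depended on the scaling and was -0.0073 without scaling, -0.22 with the 75th percentile over all probes and -0.23 with spike-in scaling. There camera at the preset correlation, which compares the list with the other miRNAs, gave adjusted p of 0.00590, 0.00706 and 0.00848.

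No member of the Treg identity and function list was called. Of its 10 tested members 8 were lower and 2 higher in infected arrays, with a median log2 difference of -0.59 (camera adjusted p = 0.0545). The list's mean relative to the uninfected mean was -0.018 in infected replicate 1 and -0.75 in infected replicate 2, and 0.24 and -0.24 in uninfected replicates 1 and 2. Its mean difference of -0.39 was -0.010 without infected replicate 2, -0.75 without infected replicate 1, -0.16 without uninfected replicate 1 and -0.62 without uninfected replicate 2. miR-155-5p, which supports Treg fitness, stood at 1.96 ± 0.04 in uninfected and 1.02 ± 0.84 in infected arrays, and miR-146a-5p, a brake on NF-kB signalling, had a log2 difference of -0.63 (adjusted p = 0.949). miR-31-5p had a log2 difference of 0.99 (adjusted p = 0.691) and miR-210-3p of -0.54. miR-10a-5p was not detected on any array. Of the T cell activation list 5 of 6 tested members were higher and 1 lower (median log2 difference 0.33, camera adjusted p = 0.316), with miR-21a-5p at 0.51 (adjusted p = 0.966), and 0 were called. This list's mean was 0.61 and -0.11 in infected replicates 1 and 2, and 0.42 and -0.42 in uninfected replicates 1 and 2.

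The other families gave no call over all tested miRNAs. The let-7 family had 7 of 8 members lower (median -0.40, camera adjusted p = 0.0545), with let-7b-5p at -0.81, and the mean was 0.23 in infected replicate 1 and -1.14 in infected replicate 2. The miR-181 family had 4 of 4 lower (median -0.60, camera adjusted p = 0.0564), with miR-181b-5p at -0.61, and both infected arrays lay below both uninfected arrays, at -0.42 and -0.75 against 0.17 and -0.17. The miR-15/16 family had 4 of 4 lower (median -0.27, camera adjusted p = 0.249), with miR-15b-5p at -0.69 and miR-15a-5p at -0.28, and the miR-23/27/24 clusters 4 of 5 (median -0.25, camera adjusted p = 0.109), with miR-27a-3p at -0.80. The miR-17 cluster and its paralogues, which promote proliferation, had 9 of 12 higher (median 0.27, camera adjusted p = 0.249), with miR-18a-5p at 0.87 and miR-17-5p at 0.48. Their mean was 0.57 and -0.08 in infected replicates 1 and 2, and 0.35 and -0.35 in uninfected replicates 1 and 2. The Dlk1-Dio3 cluster had 3 of 4 higher (median 0.45, camera adjusted p = 0.249), with miR-494-3p at 1.03 and miR-370-3p at 0.55, and the Sfmbt2 cluster 11 of 13 lower (median -0.08, camera adjusted p = 0.259), with miR-467e-5p at -0.47 and miR-669n at -0.38. Both arms of miR-142a were lower, with miR-142a-5p at -0.52, and 1 passed when adjusted over the list alone. Without scaling between arrays, where the median of all miRNAs was 0.40 against -0.010, the means of the Treg identity, let-7, miR-15/16, miR-23/27/24 and Sfmbt2 lists turned positive.

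**Figure D2:**
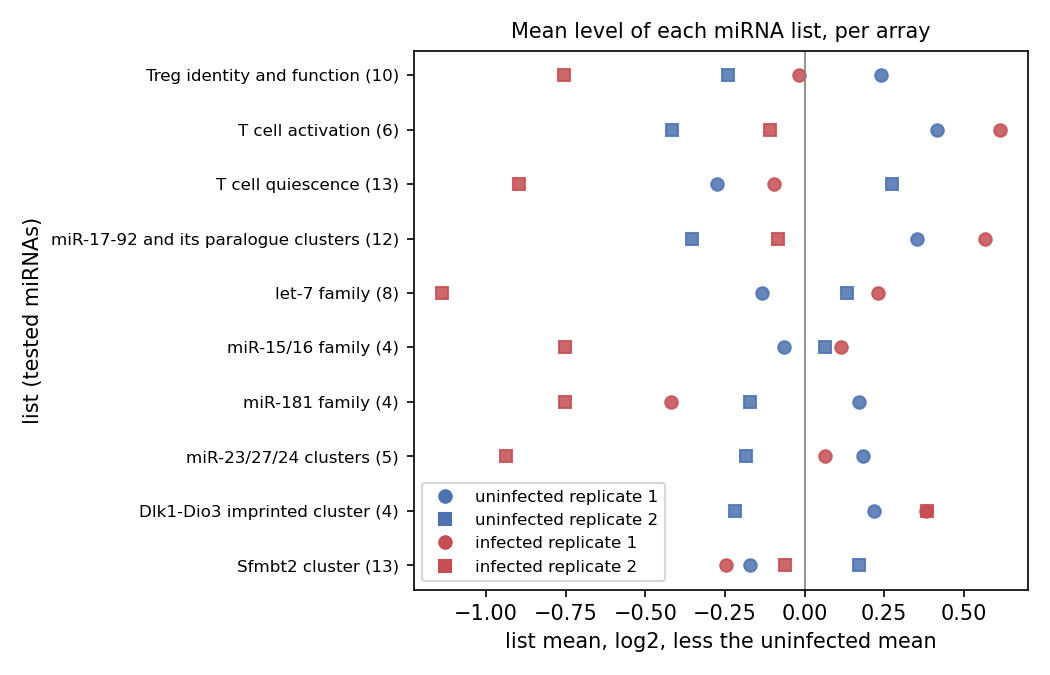
Mean log2 signal of each tested list less the mean of the uninfected arrays (x axis), with 1 point per array, blue for uninfected and red for infected, circles for replicate 1 and squares for replicate 2, and the number of tested members in brackets. The T cell quiescence list lies at -0.27 and 0.27 in uninfected and -0.10 and -0.90 in infected arrays.

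No erythroid, endothelial, platelet, stromal or other-tissue miRNA of the lists was detected on any array, and 1 of 5 myeloid ones was. The brightest miR-451a probe, the main miRNA of red cells, read 8.99 and 1.94 in uninfected and 16.8 and 3.58 in infected replicates 1 and 2, with 46.7% of its spots above background on infected replicate 1, 6.67% on uninfected replicate 1 and 0% on the other 2. Scaled to the 75th percentile it stood at 4.11% and 0.894% in uninfected and 4.15% and 1.55% in infected arrays. The myeloid miR-223-3p was the exception, well above background on uninfected replicate 1. It read 62.6 and 9.92 in uninfected and 16.6 and 5.17 in infected arrays and was detected on 2 arrays, both numbered replicate 1.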

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

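Array signal over background limits these results: 10.5% to 13.9% of spots were well above it, and dim miRNAs sit near the floor. The labelling spike-in scaling, the unmoderated variance and the concordant total gene signal (only miRNAs whose total follows their own probes) were chosen after seeing the data. Against 5 calls, all higher, limma called 0 under quantile normalization, no scaling, normexp, Agilent total gene signal, no filter on dim miRNAs, slide as a block, spike-in scaling and unmoderated variance (14 to 31 miRNAs at an unadjusted p under 0.05, and 11 with unmoderated variance), and 0 to 0 with an array left out. It called 1 with the floor at the 5th percentile, 2 among miRNAs detected on all 4 arrays, 3 with the concordant total gene signal (1 higher, 2 lower) and 10 with the deposited values (9 higher, 1 lower, 1 shared with the 5). Other settings gave 4 to 6. Under quantile normalization, no scaling and spike-in scaling the median standard errors of the 5 were 0.35, 0.33 and 0.30, against 0.49. Limma's prior degrees of freedom fell there from infinite to 4.08, 2.28 and 2.41. These calls thus ended as the prior fell, while the standard errors were no larger. With slide as a block the prior stayed infinite and the standard error was 0.63. The settings with 4 to 6 calls had an infinite prior, or 7.08 with all probes. Other causes were not tested, except that leaving out an array removes samples. The labels do not say whether the replicate numbers mark a shared batch. Across miRNAs, the deviations of same-numbered arrays from their group means correlated with r = 0.19. The arrays numbered replicate 1 had the highest r of any pair (0.969), although they lay on different slides. With the replicate block 6 were called, all higher, including the same 5, and 1 list shifted, as without it. Against 14 miRNAs at least 2-fold apart with no overlap there were 23 with the 75th percentile over all probes, 35 without scaling, 2 with normexp, 56 with total gene signal, 33 with its concordant form, 41 with the deposited values, and 15 to 49 with an array left out. Lists past the threshold numbered 1, against 4 with all probes, 4 without scaling, 4 with the brightest probe, 4 with the higher floor, 4 with spike-in scaling, 2 with quantile normalization, 3 with slide as a block, 7 without a filter, 0 with total gene signal, its concordant form, the deposited values, an estimated correlation or fry, and 0 to 6 with an array left out. Mean within-group r was 0.939, against 0.953 with normexp, 0.952 with the brightest probe, 0.972 without a filter, 0.857 with total gene signal, and 0.932 to 0.954 with an array left out. Other splits gave 0 calls at most, and 1 with all probes. The median log2 difference of all miRNAs was -0.010, against 0.22 with all probes, 0.40 without scaling and 0.21 with spike-in scaling. Without a filter 78.4% of miRNAs had no variance within the groups, which makes limma's prior unreliable there, so its counts say nothing about stability. Some directions reversed. Without scaling the mean log2 difference was 0.0863 for the Treg identity list, 0.0353 for let-7, 0.153 for miR-15/16, 0.0491 for miR-23/27/24 and 0.315 for Sfmbt2, and the difference was 0.205 for miR-15a-5p, 0.0476 for miR-467e-5p and 0.104 for miR-669n. With all probes it was 0.0992 for Sfmbt2 and 0.00322 for miR-15a-5p. All of these lie below the median of all miRNAs, 0.40 without scaling and 0.22 with all probes, so the signs followed a shift common to all miRNAs. The Sfmbt2 list was at 0.0526 with the deposited values and 0.0945 with spike-in scaling. With total gene signal miR-677-3p was at 1.54, miR-30b-5p at 0.427 and miR-467e-5p at 0.694, the last also 0.694 in the concordant form. With normexp miR-17-5p was at -0.00300, and with slide as a block miR-210-3p was at 0.230. With an array left out, which leaves a group with 1 sample assumed to vary like the other group, the sign changed within these ranges: let-7 from -1.13 to 0.229, miR-15/16 from -0.743 to 0.150 and miR-23/27/24 from -0.938 to 0.0307 (positive without infected replicate 2), T cell activation from -0.205 to 0.653 and the miR-17 cluster and paralogues from -0.105 to 0.580 (negative without uninfected replicate 2 or infected replicate 1), and Sfmbt2 from -0.313 to 0.0288. For single miRNAs the ranges were -0.265 to 1.29 for miR-21a-5p, -1.70 to 0.0147 for miR-26b-5p, -0.131 to 1.83 for miR-18a-5p, -0.00837 to 0.914 for miR-17-5p, -0.763 to 0.226 for miR-15a-5p, -0.879 to 0.0330 for miR-467e-5p and -1.02 to 0.157 for miR-210-3p. None of these reversed values passed the test except the Treg identity and let-7 lists without scaling (camera adjusted p = 0.0225 each), where camera placed them lower relative to the other miRNAs.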

Other observations

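All tests of explanations here were chosen after the results were seen. Grouped by miRBase number, a split also chosen afterwards, the 131 tested miRNAs numbered 1000 or above had a median log2 difference of 0.11 (79 higher and 52 lower in infected arrays) and the 136 others -0.11 (50 higher and 86 lower). Their medians relative to the uninfected mean were -0.02 and -0.01 in infected replicate 1, and 0.23 and -0.29 in infected replicate 2, so the contrast was seen in that array alone. Of the 5 called miRNAs, 4 belong to the higher-numbered class. In the GRCm38.p6 gene table miR-3473g overlaps Sppl2a and miR-1231 overlaps Nav1.

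The 5 called miRNAs were weighed against slide and scan, scaling, and red cell RNA. For the 3 detected in both groups, the lowest difference under quantile normalization was 1.71, with standard errors of 0.35 to 0.39. Quantile normalization was applied to values already scaled to the percentile and floored. Without scaling the 5 differences were 2.08 to 2.69. The differences thus remained under other scalings, though their size moved. These miRNAs were picked for large differences on the same arrays, so this is no independent test. Under quantile normalization the calls ended (smallest adjusted p by limma 0.179), with a prior of 4.08 degrees of freedom where it had been infinite. Normexp background correction lowered the smallest of the 5 differences to 0.47 and their median standard error to 0.24. Its offset of 50 shrinks differences of dim miRNAs, so this drop cannot decide the cause. For miR-3099-3p and miR-6921-5p, below background in the uninfected arrays, the lowest difference under quantile normalization was 1.72 and scaling stays open. Slide and scan stay open for all 5: within slide 2 the lowest difference of the 3 was 1.85, but it sets 1 uninfected array against 2 infected ones, with a standard error from the infected arrays alone (1 degree of freedom), and with slide as a block the calls ended as the standard error went from 0.49 to 0.63. Red cell RNA stays open, since miR-451a was below detection on every array, at 1.55% of the 75th percentile on infected replicate 2, between the uninfected arrays; infection, and binding of other RNA such as the parasite's, also stay open and were not tested.

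The lower T cell quiescence list was weighed against slide and scan and against infected replicate 2 alone. Within slide 2 the list's mean difference was -0.77 with a standard error of 0.69, from 1 uninfected and 2 infected arrays (1 degree of freedom), so slide and scan stay open. The mean of infected replicate 1 was -0.10, within the range of the uninfected arrays, and that of infected replicate 2 was -0.90, below both, as a difference carried by infected replicate 2 would give. The difference also depended on uninfected replicate 2: leaving that array out moved it from -0.50 to -0.23. Whether infected replicate 2 differs through infection, its RNA or its mix of sorted cells was not tested.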
